A study of Caenorhabditis elegans with 4 samples.

How the data were processed

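Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on Caenorhabditis elegans young adult hermaphrodites of the fem-2(b245) strain, grown at 20 °C. Per the labels' protocols, frozen adults were ground and fixed with 1% formaldehyde for 10 minutes, the chromatin was sheared by sonication, and single-end Illumina libraries were made. The series holds 4 samples in 2 groups: 2 RAD-51 ChIP samples and 2 input DNA samples. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures. The input samples had no file here and were not analysed.

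The authors deposited 3 peak lists. One list each was given for ChIP replicate 1 and ChIP replicate 2, and 1 list covered the whole series. Per the file headers, all coordinates refer to WormBase WS220; the submitters' processing notes name ce10 and BWA. The source column of the deposited files names MACS for the replicate lists and MACS v2 for the whole-series list. Peak-calling parameters, read filters and the use of the input in peak calling are not given in the sources used here, nor is it stated whether the whole-series list was called on pooled reads.

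The only value per peak in the deposited files is a score, and the headers do not say what it is. In the replicate lists the score started at 50.02, and 5 peaks of replicate 1 and 1 of replicate 2 stood at exactly 3100. In the whole-series list it ran from 1.30 to 50.08. If the scores are significance values of the peak caller, they also depend on depth and peak width, and they are not read here as the strength of binding. The scales differ, so scores were set against each other between lists only to correlate the replicates across shared peaks. Within a list they were used to rank or select peaks and to compare median scores between groups of peaks. No reads, counts or signal were used here. The read depth of the libraries is therefore unknown, and no peak height can be compared between samples. Exact (Clopper-Pearson) 95% intervals on shares of peaks cover counting error only, and the tests treat peaks as independent although they are not. P-values describe the positions of peaks in these lists and not the spread between animals.

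Overlaps were counted with bedtools 2.31.1 at a minimum of 1 bp. Chance overlap was taken from 1000 random placements of the peaks within their own chromosome, with a one-sided p that cannot go below 0.001. All other statistics were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. The extent of each chromosome was taken as the furthest peak end in any of the 3 lists, since no genome of this build was used. The 6 extents summed to 100235459 bp. Shares of peaks per chromosome were compared with shares of length by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes. Chromosome arms were defined by length alone, as the outer 33.3% on each side of a chromosome, and the centre as the middle 33.3%. Peaks were assigned to them by midpoint and tested in the same way. Differences between replicates were tested with Fisher's exact test, score correlations with 100000 permutations, and median scores with 10000 permutations. Mitochondrial peaks were left out of these tests.

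The functions were tested on simulated peak lists before use. With 1680 peaks placed at random, the exact test at a threshold of 0.05 called an arm excess or deficit in 9 of 100 runs. It called a departure of X in 5 of 100. It called every 1 of 100 lists made with an arm excess (mean share recovered 79.9%) and every 1 of 100 with a depleted X (mean ratio recovered 0.604). For the replicate overlap, 498 peaks with 30 shared positions planted gave a mean excess of 29.7 and were called in 20 of 20 runs, against 1 of 20 with none planted. The simulated peaks were placed independently of each other, while many neighbouring whole-series peaks lay close together. These rates therefore do not give the error rates of the tests on the real lists.

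Alternatives fixed before the data were examined were a stricter score threshold (the upper 50% of a list), support by both replicate lists, each replicate list alone, other overlap minimums (reciprocal 50%, midpoints within 200 bp), placement within the same arm or centre, arms of 25% of the length on each side, and covered length. A circular shift of peaks by 50 to 500 kb, merging of peaks closer than 10 kb, and the whole-series peaks without a replicate peak were added after the data were seen. The peaks named in the text were chosen by a rule fixed beforehand for the case of no annotation of this build: the 10 highest scores of the whole-series list and the 5 highest among peaks shared by all 3 lists. Planned tests of promoters, exons, introns, RNA genes, gene lists and GC content need a genome or annotation of WS220, which was not used here. No peak was assigned to a gene, and the fixed gene lists have no result.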

Results

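RAD-51 is the worm recombinase that coats single-stranded DNA at double-strand breaks and carries out strand exchange during meiotic and somatic repair. Its chromatin association was mapped by ChIP-seq with a rabbit polyclonal antibody in adults that contain a germline. The strain carries b245, an allele of fem-2, which encodes a phosphatase of the sex determination pathway needed for male fates, including sperm. The 4 samples are 2 RAD-51 ChIP samples and 2 input samples of 1 genotype, 1 stage and 1 antibody, so the comparisons concern the agreement of the ChIP replicates and the distribution of RAD-51 peaks along the genome.

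RAD-51 peaks covered a small part of the genome in each list. The replicate 1 list held 498 peaks, with a median width of 1032 bp, and covered 0.710% of the nuclear genome. The replicate 2 list held 634 peaks, with a median width of 1381 bp, and covered 1.04%. The whole-series list held 1695 peaks, of which 1680 were nuclear and 15 mitochondrial. Its peaks were narrower, with a median of 239 bp, and the nuclear ones covered 0.768% of the nuclear genome. Neither replicate list held a mitochondrial peak. The files name MACS for the replicate lists and MACS v2 for the whole-series list, and the number of peaks depends on sequencing depth, which is unknown.

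**Figure D1:**
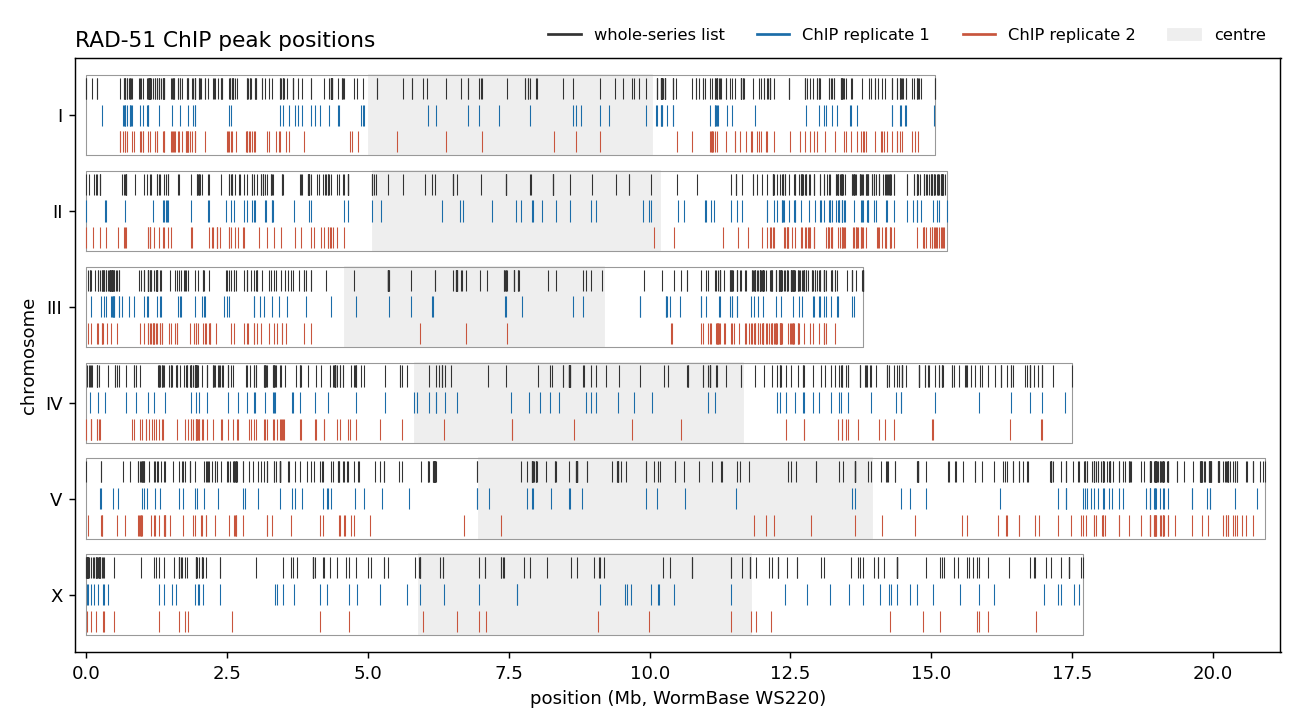
Position of every nuclear RAD-51 peak (vertical tick) along the 6 chromosomes in Mb on WormBase WS220, for the whole-series list (black, 1680 peaks), ChIP replicate 1 (blue, 498) and ChIP replicate 2 (red, 634); grey marks the centre (middle 33.3%) of each chromosome. Ticks are sparse in the grey centres of the autosomes, most clearly in replicate 2, which on IV has 73 peaks in the left arm, 6 in the centre and 17 in the right arm.

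The replicate lists shared positions far more often than random placement would give, yet most peaks were found in 1 replicate only. A replicate 2 peak overlapped 107 of the 498 replicate 1 peaks, which is 21.5% (95% interval 17.96 to 25.4). Random placement within the chromosome gave 10.3 ± 3.18 overlaps (SD over 1000 placements), so the observed number was 10.3-fold above chance (one-sided permutation p = 0.001, the smallest these placements can give). Of the shared replicate 1 peaks, 102 lay in the chromosome arms (the outer 33.3% on each side) and 5 in the centres. These counts include 8 shared peaks on X, of which 2 lay in its centre. The arms held 83.5% of all autosomal peaks in replicate 1 and 96.4% in replicate 2. The split of the shared peaks is thus nearer that of replicate 2, with or without X. Chromosomes II and V held the most shared peaks, with 27 of 110 and 24 of 85 replicate 1 peaks. Chromosome II also held the most replicate 1 peaks.

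Shared peaks had higher scores within each list. In replicate 1 the median score was 134 for the 107 shared peaks and 75.5 for the 391 others. In replicate 2 it was 198 for the 106 shared peaks and 77.9 for the 528 others (two-sided permutation p = 0.0001 for each replicate, the smallest that 10000 permutations can give). The widths of shared and other replicate peaks were not compared. Score is therefore not separated from width, which also affects overlap. Across 105 peaks that matched 1 to 1, the scores of the replicates were correlated, with Spearman's rho = 0.60 and Pearson's r = 0.66 (permutation p = 1e-05 and Benjamini-Hochberg adjusted p = 1e-05 for both, the smallest that 100000 permutations can give). Without the 2 peaks farthest from the median replicate 1 score, rho was 0.60 and r was 0.69. These correlations are across peaks, which are not independent replicates.

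By at least 1 bp, the whole-series list overlapped 235 of 498 replicate 1 peaks (47.2%, 95% interval 42.7 to 51.7) and 299 of 634 replicate 2 peaks (47.2%, 43.2 to 51.1). At a reciprocal overlap of 50% these shares were 14.1% (11.1 to 17.4) and 8.52% (6.46 to 10.97). Of the 1680 nuclear whole-series peaks, 104 overlapped both replicate lists, 225 replicate 1 only and 267 replicate 2 only. The remaining 1084 (64.5%) overlapped neither. The overlap with replicate 1 was 20.4-fold and that with replicate 2 was 15.4-fold above random placement (one-sided permutation p = 0.001 for each). The whole-series list covers the same ChIP libraries, so these lists are not independent and an overlap above random placement is built in. A circular shift of the peaks, which keeps their regional density and was chosen after the data were seen, lowered these values to 15.6-fold and 10.1-fold. Whole-series peaks with a peak in either replicate had a median score of 6.35 (596 peaks), against 4.93 for those without (two-sided permutation p = 0.0001). They were also wider. The median width was 669.5 bp for peaks overlapping both replicates, 303 bp for replicate 1 only, 275 bp for replicate 2 only and 209 bp for neither. Wider peaks overlap more readily at 1 bp, so score and width are not separated here. Of the whole-series peaks in the lowest 25% of scores, 27.1% overlapped a replicate peak, and of those in the highest 25%, 49.0% did.

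The 10 highest peaks of the whole-series list lay mainly on the right side of chromosome V. The highest, with a score of 50.08, spanned V 18886254 to 18886541. It overlapped a replicate 1 peak that ranked 66 by score in its list and a replicate 2 peak that ranked 27. Further peaks on this part of V were at 19193758 to 19195170 (score 44.73), 18979682 to 18980515 (42.56), 18982381 to 18983588 (41.99), 18882410 to 18883897 (33.72) and 14755449 to 14756073 (37.70). The one at 19193758 had the highest score of replicate 1, tied at 3100, and ranked 3 in replicate 2. The peak at 14755449 overlapped no peak of either replicate. The V peaks at 18882410 and 18886254 lie closer than 10 kb to each other, as do those at 18979682 and 18982381. Merging would make each pair 1 region, so counts among the highest peaks are not counts of separate regions.

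The other high peaks were at II 12843798 to 12845997 (score 45.50), X 11442158 to 11443779 (41.02), III 2497101 to 2501790 (36.61) and I 4540299 to 4546247 (33.66). Among them, only the X peak overlapped both replicate lists, at rank 29 in replicate 1 and rank 15 in replicate 2. The II peak was matched in replicate 2 alone, the III peak in replicate 1 alone, where it stood at the tied highest score, and the I peak in neither. In all, 6 of the 10 had a peak in both replicates, and 9 of the 10 lay in an arm, the exception being the X peak. The 5 highest peaks shared by all 3 lists were the V peaks at 18886254, 19193758, 18979682 and 18982381 and the X peak. These coordinates are not matched to genes, because no annotation of this build was used.

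The X chromosome, which is largely silent in the worm germline, held fewer RAD-51 peaks than its length predicts. In the whole-series list 169 of 1680 nuclear peaks were on X, or 10.1% (95% interval 8.66 to 11.6), where its length predicts 17.6%. The ratio of observed to expected peaks was 0.570 (95% interval 0.491 to 0.657; exact binomial p = 3.65e-18). X was low in both replicates too, at a ratio of 0.694 (0.538 to 0.876) in replicate 1 and 0.268 (0.182 to 0.379) in replicate 2. The replicates differed from each other, with 12.2% of replicate 1 peaks and 4.73% of replicate 2 peaks on X (Fisher's exact p = 4.76e-06, adjusted p = 4.76e-06). X was below expectation in both lists, but not by the same amount. In the whole-series list the X centre held 35 peaks, against 227 in the autosomal centres. These counts were 14 against 72 in replicate 1 and 7 against 22 in replicate 2. X makes up 17.6% of the length and the autosomes 82.4%. In the centres X was thus below expectation in the whole-series list and near it in replicate 1. It was not below it in replicate 2, which had only 7 peaks in the X centre. This split was not tested. No cause of the X deficit was tested, germline silencing, mappability and recovery of X chromatin included.

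In the whole-series list, chromosomes I and III held more peaks than their length predicts. These ratios are shares of all nuclear peaks, so the low count on X raises those of the autosomes. The autosomes were not tested among themselves, and the part of X in their ratios is not separated. Chromosome III had 292 peaks, a ratio of 1.26 (95% interval 1.13 to 1.40; exact binomial adjusted p = 8.52e-05), and chromosome I had 310, a ratio of 1.23 (1.11 to 1.36; adjusted p = 0.000261). Chromosome III also passed the test in replicate 1 (1.27, exact adjusted p = 0.0380) and replicate 2 (1.55, adjusted p = 7.16e-07). Chromosome I passed in replicate 2 (1.28, exact adjusted p = 0.00575) but not in replicate 1 (1.14, adjusted p = 0.210). Neither passed among the 104 peaks supported by both replicates (III at 1.19 and I at 1.09, exact adjusted p = 0.570 and 0.681). X, at 0.490, did not pass there after adjustment either (exact adjusted p = 0.0840). Chromosome III did not pass among the 1084 peaks without a replicate peak (1.11, exact adjusted p = 0.201). Chromosome II was at 1.05 in the whole-series list (exact adjusted p = 0.506), and was high in both replicate lists, at 1.45 in replicate 1 (adjusted p = 0.000287) and 1.39 in replicate 2 (adjusted p = 0.000164). Chromosomes IV and V did not pass the test in any of the 3 lists, with ratios between 0.805 and 1.03.

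**Figure D2:**
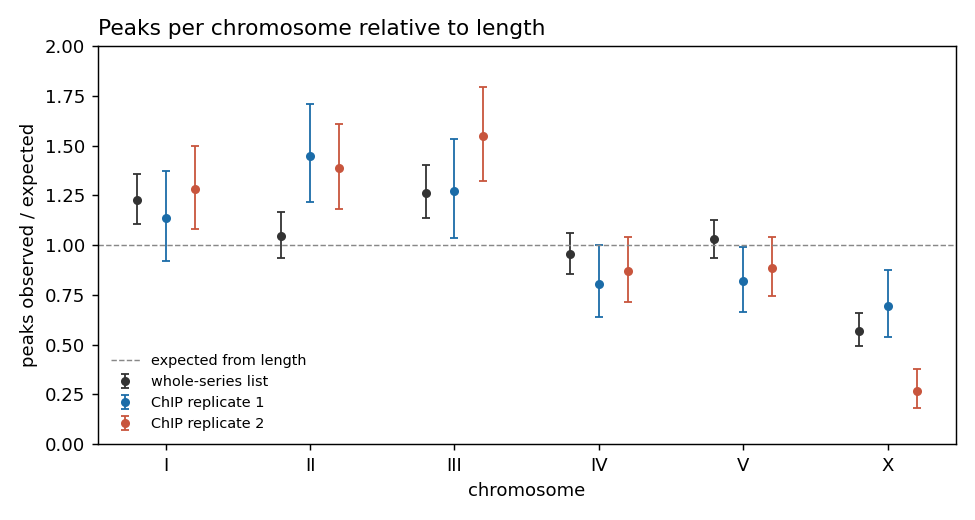
Ratio of observed to expected RAD-51 peaks (vertical axis, no unit) for each chromosome, where the expectation is the chromosome's share of nuclear length (dashed line at 1). Points are the 3 lists and bars are exact 95% intervals of counting error; X lies below 1 in every list, at 0.570, 0.694 and 0.268, and III above 1 in every list.

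On the autosomes, RAD-51 peaks were concentrated in the chromosome arms. Worm autosomes have arms, where most crossovers occur and repeats are frequent, and gene-dense centres; here both were set by length alone. In the whole-series list 1284 of 1511 autosomal peaks (85.0%, 95% interval 83.1 to 86.7) lay in the arms, which make up 66.7% of the length (exact binomial p = 1.41e-58). Peak density was 2.83-fold higher in the arms than in the centres in this list, against 2.53-fold in replicate 1 and 13.2-fold in replicate 2. Left and right arms contributed 616 and 668 peaks. The arms held 365 of 437 autosomal peaks in replicate 1 (83.5%, 79.7 to 86.9; exact p = 2.61e-15) and 582 of 604 in replicate 2 (96.4%, 94.5 to 97.7; exact p = 1.32e-73). Replicate 2 thus had the higher share (Fisher's exact p = 1.48e-12, adjusted p = 2.96e-12), with 22 autosomal peaks in the centres against 72 in replicate 1.

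Each autosome showed this distribution in the whole-series list. The share in the arms was 90.0% on I, 89.2% on II, 83.9% on III, 82.1% on IV and 80.6% on V (highest exact binomial adjusted p = 1.03e-08, for IV). All 5 autosomes also passed in replicate 2, with shares from 93.8% on IV to 99.3% on II, where 1 of 134 peaks lay in the centre. In replicate 1, 4 autosomes passed and IV, at 72.9%, did not (exact adjusted p = 0.311). On IV the test also failed for the upper 50% of the whole-series list by score, with a share of 72.2% (exact adjusted p = 0.198).

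The X chromosome also had an excess of peaks in its arms, and for unmerged peaks it lay in the left arm. It had 82 whole-series peaks in the left arm, 35 in the centre and 52 in the right arm, and after merging of peaks closer than 10 kb it had 45, 23 and 39 regions. Both arms held 134 of 169 X peaks (79.3%, 95% interval 72.4 to 85.1; exact binomial adjusted p = 0.000415). The difference from the autosomal share of 85.0% did not pass the test (Fisher's exact p = 0.0576). The replicate lists gave 77.0% in replicate 1 and 76.7% in replicate 2, and neither passed by itself (exact adjusted p = 0.123 and 0.333, with 61 and 30 X peaks).

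**Figure D3:**
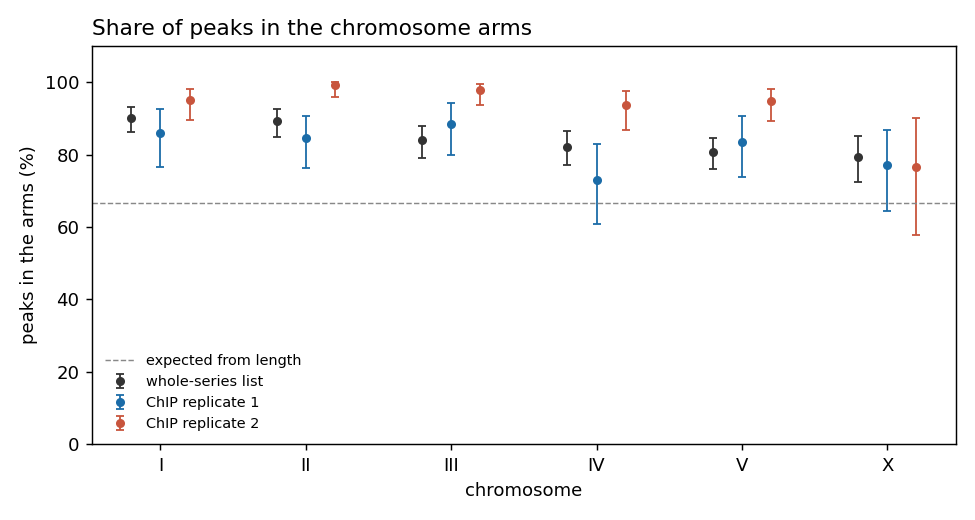
Share of RAD-51 peaks in the arms (outer 33.3% on each side) of each chromosome in percent, with exact 95% intervals of counting error, for the 3 lists; the dashed line marks the 66.7% expected from length. The points lie above the line on every chromosome, replicate 2 reaches 99.3% on II, and the intervals of IV in replicate 1 and of X in both replicates cross the line.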

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

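The whole-series list held 15 peaks on mitochondrial DNA, a molecule that the comparisons above leave out and on which neither replicate list had a peak. They ran from position 9 to 12721 and covered 73.8% of that span. Their scores lay between 8.37 and 22.81, and all 15 exceeded the list's median of 5.40. No input value was used here, so this signal has no background measured beside it.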

How the results depend on the processing

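The lower share of X and the higher share of the autosomal arms kept their direction in every alternative list that was tested. Both passed the exact test in these lists, for X before adjustment over the chromosomes. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, were not analysed here. The planned tests that need annotation or sequence were not run. Without 1 replicate at a time (the other replicate's own list), X ranged from 0.268 to 0.694 of its expected peaks and the arms from 1.25 to 1.45. In the other alternatives X ranged from 0.490 (peaks in both replicates, exact p = 0.0140) to 0.655 (covered length, no test), and the arms from 1.20 (no replicate peak) to 1.45 (peaks in both replicates).

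The number of peaks fell from 1695 to 850 in the upper 50% by score and to 104 with support from both replicates, where the covered length fell from 779 to 102 kb; the replicate lists alone held 498 to 634 peaks. The fold of replicate overlap over chance ranged from 7.02 (circular shift, added after the data were seen) to 42.2 (midpoints within 200 bp), each at a permutation p of 0.001. The share of replicate 1 peaks recovered in replicate 2 was 16.1% at a reciprocal overlap of 50%, 11.8% by midpoints and 26.9% in the upper 50% by score of each list, and 16.7% of replicate 2 peaks were recovered in replicate 1. A reciprocal overlap of 50% lowered the share found in the whole-series list to 14.1% for replicate 1 and 8.52% for replicate 2, and that of whole-series peaks found in replicate 1 and replicate 2 to 4.17% and 3.21%; the narrower whole-series peaks limit this measure by construction. In the upper 50% by score of each list, 56.2% of replicate 1 and 46.7% of replicate 2 peaks were in the whole-series list, and 21.8% and 21.1% of its peaks were in replicate 1 and replicate 2.

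Single chromosomes were less stable. With the 104 peaks supported by both replicates, the ratios of I, III and X were 1.09, 1.19 and 0.490 and no longer passed after adjustment over the chromosomes, with fewer peaks tested. Chromosome III was at 1.11 among peaks with no replicate peak (added), also not passing; the cause was not tested. With 1 replicate left out, I ranged from 1.14 to 1.28 and II from 1.39 to 1.45, against 1.05 in the whole-series list. The unknown read depth limits any reading of differences in peak number between the lists.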

Other observations

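The tests of the chromosome ends, of spacing, of left against right arms and of the first 1 Mb of X were chosen after those patterns were seen; the others in this part, merging and rotation included, were added after the lists had been examined but before their own results were seen.

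Whole-series peaks were uneven between the 2 arms of some chromosomes, but the unevenness of this list did not pass once neighbouring peaks were merged; the replicate lists were not merged. On chromosome II the right arm held 139 peaks and the left 100, with 61 and 32 in replicate 1 and 81 and 52 in replicate 2 (exact binomial adjusted p = 0.0414, 0.0208 and 0.0446). After whole-series peaks closer than 10 kb were merged, II had 77 regions on the right and 69 on the left (exact adjusted p = 0.878). The peaks that overlap both replicate lists were split 10 and 10 on II, while I had 13 left and 3 right, IV 10 and 3, V 7 and 19 and X 7 and 0. The lowest exact adjusted p among these was 0.0579, for I, V and X alike. The left arm was higher in the whole-series list on IV (133 against 97, exact adjusted p = 0.0416) and on X (82 against 52, exact adjusted p = 0.0414), and merging left 83 against 64 on IV and 45 against 39 on X (exact adjusted p = 0.824 and 0.878). The replicates differed on IV, with 73 left and 17 right in replicate 2 (exact binomial adjusted p = 1.17e-08) and 29 left and 22 right in replicate 1 (exact adjusted p = 0.715; Fisher's exact p = 0.00307 for the difference). A difference between the 2 arms of a chromosome thus passed in all 3 lists and in the merged regions for 0 of 6 chromosomes, and it stays open.

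The first 1 Mb of X, at the end that carries the X pairing centre, held 32 of 169 whole-series X peaks (18.9%, 95% interval 13.3 to 25.7), where its length predicts 5.65% (exact binomial adjusted p = 7.00e-09). It held 8 of 61 X peaks in replicate 1 (13.1%, exact adjusted p = 0.0211) and 6 of 30 in replicate 2 (20.0%, exact adjusted p = 0.0120). After peaks closer than 10 kb were merged, 12 of 107 X regions lay there, or 11.2% (exact adjusted p = 0.0211), the lowest of these shares. A concentration of RAD-51 at this end of X is a hypothesis, and splitting of broad regions may account for part of the excess, since the ratio to expectation fell from 3.35 to 1.98 with merging. Merging also lets dense regions count once, and no input value was used to judge the background there. The 1 Mb bins with the most peaks lay on other chromosomes. They were III from 12 Mb in the whole-series list (62 of 292 peaks on III), II from 13 Mb in replicate 1 (24 of 110) and III from 12 Mb in replicate 2 (34 of 135). The p-values above are not adjusted over such bins, so the excess is not shown to be particular to this end of X.

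Whole-series peaks lay closer together than the density of their arm or centre predicts. Of 1674 gaps between neighbouring peaks, 579 were under 5 kb, against a mean of 177 and a maximum of 211 in 1000 random placements within the same arm or centre (one-sided permutation p = 0.001, the smallest possible). The placements were even within each arm or centre, so uneven density inside them was not accounted for. Splitting of broad regions into several peaks was not separated from clustering of sites either. The median whole-series score was 5.17 for 1284 autosomal peaks in the arms and 5.95 for 227 in the centres, a difference of -0.785 for arms minus centres (two-sided permutation p = 0.0091).

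The concentration of autosomal peaks in the arms was weighed against technical explanations. Splitting of broad regions into several peaks would need the excess to vanish after merging, and 84.8% of 875 merged regions still lay there (95% interval 82.2 to 87.1). Chance position of clustered peaks is argued against by rotation of the peaks within each autosome, in which 1000 rotations gave at most 1248 peaks in the arms against 1284 observed (one-sided permutation p = 0.001). Uneven mappability, repeats and uneven recovery of arm chromatin were not tested, because neither the input nor the genome was used, and they stay open. No biological explanation was tested, since the design has no group to contrast.

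The modest recovery of replicate 1 peaks in replicate 2 was weighed in the same way. If unshared peaks were only calls near the threshold, most of the highest-scoring peaks should recur. Of the 125 peaks in the highest 25% of replicate 1 scores, 51 did (40.8%, 95% interval 32.1 to 49.9), which falls short of 50% by a narrow margin. A peak high in replicate 1 may still miss the replicate 2 threshold, and shared replicate 1 peaks had the higher median score (134 against 75.5). A part for calls near the threshold therefore stays open. If unshared peaks were background spread evenly by length, they should follow length. Yet 269 of 338 autosomal replicate 1 peaks without a replicate 2 peak lay in the arms (79.6%, 95% interval 74.9 to 83.8). Background that gathers in the arms, through repeats or mappability, would also give such a share, so this value cannot tell background from real sites. Neither value decides between background, real sites and a mixture of them, and a difference in depth or antibody recovery between the replicates stays open. No biological explanation was tested.

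Peaks also lay at the left ends of the chromosomes, where coordinates start at the telomere. Right ends could not be examined in this way, because each extent was itself set by the furthest peak end. A pattern particular to left ends is therefore not shown. Of the whole-series peaks, 8 started within 5 kb of a left end, and of these 3 were on X and 2 on I. They included I 1 to 437 (score 18.17), II 95 to 254 (19.86) and X 1 to 331 (5.27). Replicate 1 had a peak at II 2 to 939, and replicate 2 had peaks at II 2 to 1093 and IV 2 to 1158. Such peaks were on 5 of the 6 chromosomes, against at most 4 in 1000 rotations that keep the clustering (one-sided permutation p = 0.001), with p = 0.16 for replicate 1 and 0.021 for replicate 2. The 5 kb window was set after these peaks were seen, so chance position of clustered peaks at the left ends stays open. Reads of telomeric repeats collected at the assembled ends may give such peaks in any chromatin sample, and the input needed to test that was not analysed here.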
